A study of Danio rerio with 48 samples.

How the data were processed

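Genomic DNA from zebrafish (Danio rerio, TAB strain) was sequenced at low depth to measure copy number across the genome. The sequenced material was 3 malignant peripheral nerve sheath tumours (MPNST, tumours of the sheath that surrounds peripheral nerves) and 3 normal tails. In the tumour labels, 2 tumours came from fish with a mutation in a ribosomal protein (rp) gene and 1 came from fish with a p53 mutation. The rp gene that was mutated in each fish is not given in the sources used here. The series also lists 42 array comparative genomic hybridisation samples (31 rp tumours, 5 p53 tumours and 6 comparisons of normal tail with normal tail), which were not analysed here.

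The deposited table holds read counts per library in windows of 100 kb, which the authors produced from aligned reads with a quality score of 10 or greater on the Zv8 assembly, per the file headers. Sequencing was done on an Illumina GAIIx instrument with Sequence Control Software 2.6.26, and base calling used OLB 1.6.0 or CASAVA 1.6.0, with 41-nucleotide reads, per the file headers. Libraries carried barcodes and were separated and trimmed with fastx_toolkit 0.0.13, per the same headers. The aligner, and any treatment of duplicate reads or repeats, are not given in the sources used here. Reads of the rp pairs were pooled from 3 sequencing runs and those of the p53 pair from 2 other runs, so that both members of a pair shared their runs while the p53 pair shared none with the rp pairs.

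Each tumour was paired with a tail through the specimen names and column names. For rp tumour 2, the title of its tail carries a specimen name that differs from that of the tumour in its last digit, while the column names put them together, and this tail was used as its pair. Pairing was also checked in the counts. After the mean of the tumours and the mean of the tails had been subtracted from log counts, the correlation across windows between a tumour and its own tail was 0.47 for rp tumour 1, 0.52 for rp tumour 2 and 0.64 for the p53 tumour, the highest among the 3 tails for each tumour. Shared runs within a pair also enter these correlations. Across chromosomes, on counts summed per chromosome, the correlation with the own tail was 0.55 for rp tumour 1, -0.03 for rp tumour 2 and 0.21 for the p53 tumour. At that level the counts did not tell the tail of rp tumour 2 from the others. Tails are numbered by pair below. No label says that tumours came from different fish families, and each group holds at most 2 tumours.

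The table has 13242 windows, of which 13241 lie on the 25 numbered chromosomes and 1 is the mitochondrial genome, which was left out of all comparisons. Windows were kept when the mean count over the 6 libraries was at least 0.25 times that of the median window (39.1 reads), which kept 12191 windows and removed 1050, of which 59 had no read in any library. Kept windows held between 98.9% and 99.1% of the reads of each library. The median kept window held 136 reads in tail 1, 170 in rp tumour 1, 264 in tail 2, 221 in rp tumour 2, 71 in tail 3 and 66 in the p53 tumour. Counting error alone thus gave a standard deviation of 8.57%, 7.67%, 6.15%, 6.73%, 11.9% and 12.3% of the median window in the same order. Bootstrap intervals below are 95% intervals and cover variation between windows, not between animals.

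Tumours were compared with tails by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on counts, with pair as a block and trimmed-mean (TMM) factors computed from the windows. The test was run on counts summed per chromosome and on single windows, with Benjamini-Hochberg adjustment at 0.05. A term for the p53 pair was added on chromosome sums to test whether the tumour effect differed between the p53 pair and the rp pairs. With 1 p53 tumour, this test assumes that it varies as the rp tumours do. P-values refer to the spread around this fit, with a variance that edgeR shared across chromosomes or windows. The degrees of freedom were 26.3 for chromosomes and 35.3 for windows in tumours against tails, and came mostly from this sharing. P-values and SEs thus measure the spread among these pairs only in part.

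Each tumour was also described alone, with no test. The log2 ratio of tumour reads plus 1 over reads of its own tail plus 1 was centred on the median kept window, and the value of a chromosome was the median over its windows, with a moving block bootstrap (blocks of 10 windows, 1000 draws). A chromosome was called gained or lost when its value passed 0.2 on the log2 scale and also passed the largest chromosome value of any tail-over-tail ratio, which was 0.20 on chromosome 10 for tail 1 over tail 3. Parts of chromosomes were found by penalised least-squares segmentation of the same ratios after extreme values had been limited over 11 windows, with a penalty of 40 times the squared noise and at least 5 windows per segment. A segment at least 0.2 from its chromosome median counted as a partial change. Focal runs were at least 2 adjacent windows lying 1 or more, on the log2 scale, from their chromosome median. Chromosome values of pairs of tumours were correlated with 100000 permutations of chromosomes, two-sided, and adjusted over 3 pairs of tumours.

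The comparison of tumours with tails and the calls made per tumour were tested on simulated data. The test of the p53 pair against the rp pairs, the correlations, partial losses, deleted focal runs and the alternatives were not. On simulated windows compared between tumours and tails, edgeR recovered 34 of 100 with a 1.5-fold change, 49 of 50 with a 2-fold change and 46 of 50 with a 0.5-fold change, and called 7 of 11991 unchanged windows. On simulated sets of 25 chromosomes, it recovered 36 of 40 changed 1.2-fold, with 9 of 210 unchanged chromosomes called. It recovered 40 of 40 changed 1.333-fold, with 7 of 210 called. At both folds the false calls were thus a larger share of all chromosome calls than the level set for adjusted p-values. Chromosomes that pass this level are therefore less certain than their adjusted p-values state. In these edgeR simulations every tumour carried the same fold on a changed chromosome. Real tumours could differ, as on chromosome 18, at 0.46 in rp tumour 1, 0.44 in rp tumour 2 and -0.45 in the p53 tumour. Rates of recovery and of false calls by edgeR were not measured for tumours that differ in this way. The per-tumour procedure recovered 80 of 80 changed chromosomes at the depth of each tumour and called 0 of 150 unchanged chromosomes. It also recovered 20 of 20 partial changes and 20 of 20 focal runs of 4-fold amplification in each. These simulated windows varied independently, with no differences between tails along or between chromosomes, and the tail limit was not applied. They therefore do not show how often such differences are called.

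Tests, thresholds, named regions and most alternatives were fixed before the data were examined. The regions named below are all chromosomes past the chromosome test, chromosomes called in a tumour (the 5 highest and 5 lowest with values), the 5 longest partial changes of each tumour by number of windows, and its 5 highest and 5 lowest focal runs. Alternatives were DESeq2 1.42.0, other scalings and centrings, other window filters, other thresholds, a fit without the pair block, another reference tail and leaving out each pair. No genome sequence or annotation of Zv8 was used here, so no gene was placed on a window and windows were not corrected for GC content.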

Results

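Low-depth sequencing of genomic DNA was used to measure chromosome copy number in 3 zebrafish MPNST, each set against a normal tail. The question posed by the design is which chromosomes and regions are gained or lost in these tumours, and whether tumours from rp mutant fish and from p53 mutant fish carry the same changes. Heterozygous mutation of many rp genes and homozygous mutation of p53, a tumour suppressor gene, both predispose zebrafish to this tumour type. The deposited read counts amounted to 1650778 reads in tail 1, 2306217 in rp tumour 1, 3115235 in tail 2, 2881549 in rp tumour 2, 971289 in tail 3 and 901948 in the p53 tumour. Positions are given on Zv8, in windows of 100 kb.

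Across the 3 pairs, chromosomes 25, 10, 22 and 11 held more reads in tumours than in tails, and chromosomes 15, 17, 8 and 5 held fewer. Chromosome 25 was the highest, at a log2 fold change of 0.77 (SE 0.17, adjusted p = 0.0013, edgeR quasi-likelihood test), followed by chromosome 10 at 0.64 (SE 0.14, adjusted p = 0.0013). Chromosome 11 rose by 0.38 (SE 0.14, adjusted p = 0.039) and chromosome 22 by 0.34 (SE 0.11, adjusted p = 0.028). Chromosomes 15 and 17 were the lowest, both at -0.40 (SE 0.11, adjusted p = 0.011, and SE 0.13, adjusted p = 0.026), followed by chromosome 8 at -0.37 (SE 0.14, adjusted p = 0.039) and chromosome 5 at -0.34 (SE 0.12, adjusted p = 0.032). Except for chromosome 15, which missed the limit in rp tumour 1, each of these 8 chromosomes was also called in the same direction in each of the 3 tumours taken alone. Without pair 2, whose tumour holds the amplified windows described for chromosome 25, this chromosome stood at 0.48 (SE 0.19, adjusted p = 0.14) and chromosome 10 at 0.77 (SE 0.26, adjusted p = 0.083). Chromosome 10 passed under each alternative except leaving out pair 1 or pair 2. Chromosomes 5 and 8 did not pass with DESeq2 (adjusted p = 0.081 and 0.053), with all windows (0.072 and 0.087) or without windows over 2 times the median tail window (0.13 and 0.062). With library totals, chromosomes 25, 11 and 22 did not pass (adjusted p = 0.057, 0.058 and 0.090), and with all windows chromosome 11 did not (0.053). Without pair 3, chromosomes 8, 15, 17 and 22 did not pass (adjusted p = 0.097, 0.076, 0.077 and 0.16). In the simulated chromosome sets, false calls by edgeR exceeded the level of the adjustment, so its adjusted p-values for chromosomes may be too small.

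At the resolution of single windows, 645 of 12191 passed the same test, 429 of them higher and 216 lower in tumours. Chromosome 10 held 196 of the higher windows, 46.8% of its 419 kept windows, and chromosome 25 held 135 of its 373, or 36.2%. Chromosome 11 added 44. Among the lower windows, 56 lay on chromosome 15, 39 on chromosome 5, 35 on chromosome 17, 31 on chromosome 8 and 23 on chromosome 3. Chromosomes 12, 18 and 24 held none. Neighbouring windows are not independent, so these counts follow the changed chromosomes. With library totals in place of TMM factors, 5 chromosomes passed, 1 higher and 4 lower, against 4 and 4 in the main analysis, and 340 windows did (207 higher, 133 lower). With DESeq2, 437 windows were higher and 67 lower. Without the pair block, no window passed by edgeR (1350 had an unadjusted p under 0.05), and without pair 1 or without pair 2 no chromosome did (4 and 5 under 0.05). For windows, 52 passed without pair 1 (49 higher, 3 lower), 7 without pair 2 (3 higher, 4 lower) and 1978 without pair 3 (1113 higher, 865 lower). In these fits edgeR shared the variance across windows to different degrees (53.1, 12191 and 12191 degrees of freedom), so the counts are not like for like. The same holds for chromosomes, whose fits had 2.27 degrees of freedom without pair 1 and 25 without pair 2 or without pair 3.

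Taken one by one, each tumour had many gained and lost chromosomes, while tails differed little from each other. The limit for a call was passed by 18 of 25 chromosomes in rp tumour 1 (10 gained, 8 lost), 14 in rp tumour 2 (8 gained, 6 lost) and 16 in the p53 tumour (8 gained, 8 lost). Chromosome values had a standard deviation of 0.38, 0.31 and 0.36 on the log2 scale in these tumours. In the 3 tail-over-tail ratios it lay between 0.066 and 0.079, and the largest single value was 0.20.

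**Figure D1:**
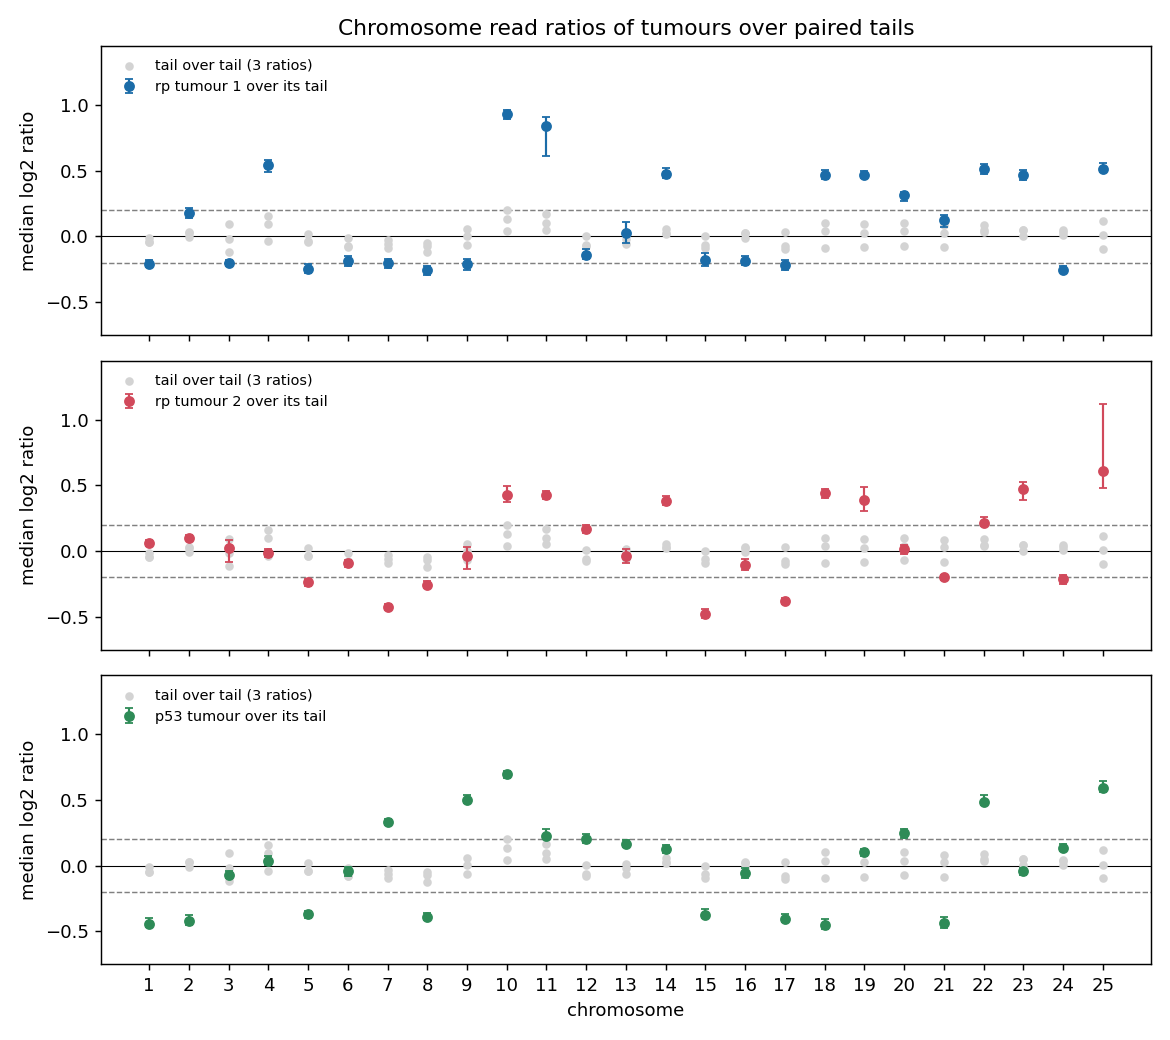
Median log2 read ratio per chromosome (y axis) for chromosomes 1 to 25 (x axis) in rp tumour 1, rp tumour 2 and the p53 tumour over their own tails, with bars for 95% block bootstrap intervals, grey points for the 3 tail-over-tail ratios and dashed lines for the call limit of 0.20. Chromosomes 10, 11, 22 and 25 lie above the upper line in all 3 tumours, and chromosome 18 lies above it in both rp tumours and at -0.45 in the p53 tumour.

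Gains of chromosomes 10, 11, 22 and 25 and losses of chromosomes 5, 8 and 17 were called in all 3 tumours. Chromosome 10 reached 1.90-fold the median window in rp tumour 1, 1.34-fold in rp tumour 2 and 1.62-fold in the p53 tumour. For chromosome 25 the values were 1.42-fold, 1.52-fold and 1.51-fold. The value of rp tumour 2 includes 99 amplified windows, and its other 274 windows had a median log2 ratio of 0.44. A call in at least 2 tumours was made for 9 gained chromosomes, adding 14, 18, 19, 20 and 23 to those above, and for 7 lost chromosomes, adding 1, 7, 15 and 24. Chromosomes 6, 13 and 16 were called in none. Which calls were shared by all 3 tumours depended on the centring and on the reference tail. With ratios centred on their most frequent value, these were the gains of chromosomes 10 and 25 and 0 losses, and on library totals they were the gain of chromosome 25 and the loss of chromosome 8. Against tail 1, chosen after the data had been seen, rp tumour 2 was not called on chromosomes 8 (-0.197) and 22 (0.139).

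In rp tumour 1, the highest chromosomes were 10 (0.93, interval 0.89 to 0.96), 11 (0.84, 0.61 to 0.91), 4 (0.54, 0.49 to 0.58), 22 (0.51, 0.47 to 0.55) and 25 (0.51, 0.49 to 0.56), all in log2 units. Chromosomes 14, 18, 19, 20 and 23 were also gained. Its losses were shallow, with the lowest values on chromosomes 24 (-0.26), 8 (-0.26), 5 (-0.25), 17 (-0.22) and 1 (-0.21), and with chromosomes 3, 7 and 9 also called. When the ratios were centred on their most frequent value, which moved the median window by 0.18, this tumour had 13 gained chromosomes and 0 lost ones. Tail 1 over tail 2 followed the values of both rp tumours, measured against tail 3, with slopes of 0.12 for rp tumour 1 and 0.14 for rp tumour 2 across chromosomes. Against tail 2 instead, an alternative chosen after the data had been seen, chromosomes 10 and 11 reached 1.10 and 1.03, and 20 chromosomes were called, with chromosome 6 added as lost (-0.26 against -0.19) and chromosome 21 as gained (0.23 against 0.13), while chromosome 15 stayed within the limit at -0.17.

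In rp tumour 2, chromosome 25 was highest at 0.61 (0.48 to 1.12), followed by chromosomes 23 (0.47), 18 (0.44), 11 (0.43) and 10 (0.42), with 14, 19 and 22 also gained. The rank of chromosome 25 rests on its 99 amplified windows, since its other 274 windows had a median of 0.44. Chromosome 15 was lowest at -0.48 (-0.51 to -0.44), followed by chromosomes 7 (-0.42), 17 (-0.38), 8 (-0.26) and 5 (-0.23), with 24 also lost. Centring on the most frequent value gave 7 gained and 7 lost chromosomes. Against tail 1, by the same later choice, chromosomes 8 (-0.20) and 22 (0.14) were no longer called and chromosome 21 was lost (-0.30). Chromosomes 10 and 11, which rose against the other tail in rp tumour 1, fell here to 0.27 and 0.29 and stayed called.

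The p53 tumour had its highest values on chromosomes 10 (0.70, 0.67 to 0.72), 25 (0.60, 0.56 to 0.64), 9 (0.50), 22 (0.49) and 7 (0.33). Chromosomes 11, 12 and 20 were gained as well. Its lowest values were on chromosomes 18 (-0.45, -0.48 to -0.40), 1 (-0.44), 21 (-0.43), 2 (-0.42) and 17 (-0.40), and chromosomes 5, 8 and 15 were lost too. Centring on the most frequent value gave 5 gained and 8 lost chromosomes, and centring on library totals gave the same 2 counts. On library totals the limit for a call, set by the tails, rose to 0.34, and the median window moved by -0.12 in rp tumour 1, which then had 9 gained and 3 lost chromosomes. Rp tumour 2 had 3 gained and 4 lost chromosomes on that centring.

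Chromosomes of the p53 tumour mostly kept 1 level along their length over its own tail, while levels within chromosomes differed in both rp tumours, and also between normal tails. Segmentation found 1 segment on each of 24 chromosomes in the p53 tumour, against 2 chromosomes in rp tumour 1, 6 in rp tumour 2 and 4 in tail 1 over tail 2, normal tails of the same runs as the rp tumours. Partial changes numbered 23 in rp tumour 1, 37 in rp tumour 2 and 1 in the p53 tumour, against 11 in tail 1 over tail 2, and 57 and 66 in tails 1 and 2 over tail 3, which came from other runs. In a check chosen after the data had been seen, 9 of 23 in rp tumour 1 and 31 of 37 in rp tumour 2 also lay 0.2 or more from the chromosome median, in the same direction, against the other tail of the same runs. The p53 tumour had 6 with a penalty of 25, and 48 against the summed tails, which brought in tails of other runs. The median window of the p53 pair held 66 and 71 reads, against 136 to 264 in the rp pairs, and the difference in segments between tumours was not tested.

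The clearest partial change of rp tumour 1 lay on chromosome 11. Its first 13.9 Mb (windows 1 to 13900000) had a log2 ratio of -0.21, near the lost chromosomes of this tumour, while the rest of the chromosome stood at 0.95, a step of 1.16 (interval 1.10 to 1.23) over 134 and 288 windows. The other 2 pairs had no such step, with 0.00 (-0.04 to 0.04) in rp tumour 2 and 0.02 (-0.06 to 0.08) in the p53 tumour. By number of windows (141), the longest partial change of rp tumour 1 covered the first 15.4 Mb of chromosome 13, at -0.29 against a chromosome median of 0.03. The remaining 3 of its 5 longest lay on chromosome 4 (26700001 to 71600000, at 0.31 against 0.54, over 110 windows, since 345 of the 717 windows of this chromosome had been removed for low counts), chromosome 9 (44700001 to 54800000, at -0.41 against -0.21) and chromosome 2 (49000001 to 58000000, at -0.10 against 0.18). Those 3 did not hold against tail 2, the other tail of the same runs, where their distances from the chromosome median were -0.055, -0.0028 and -0.13.

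**Figure D2:**
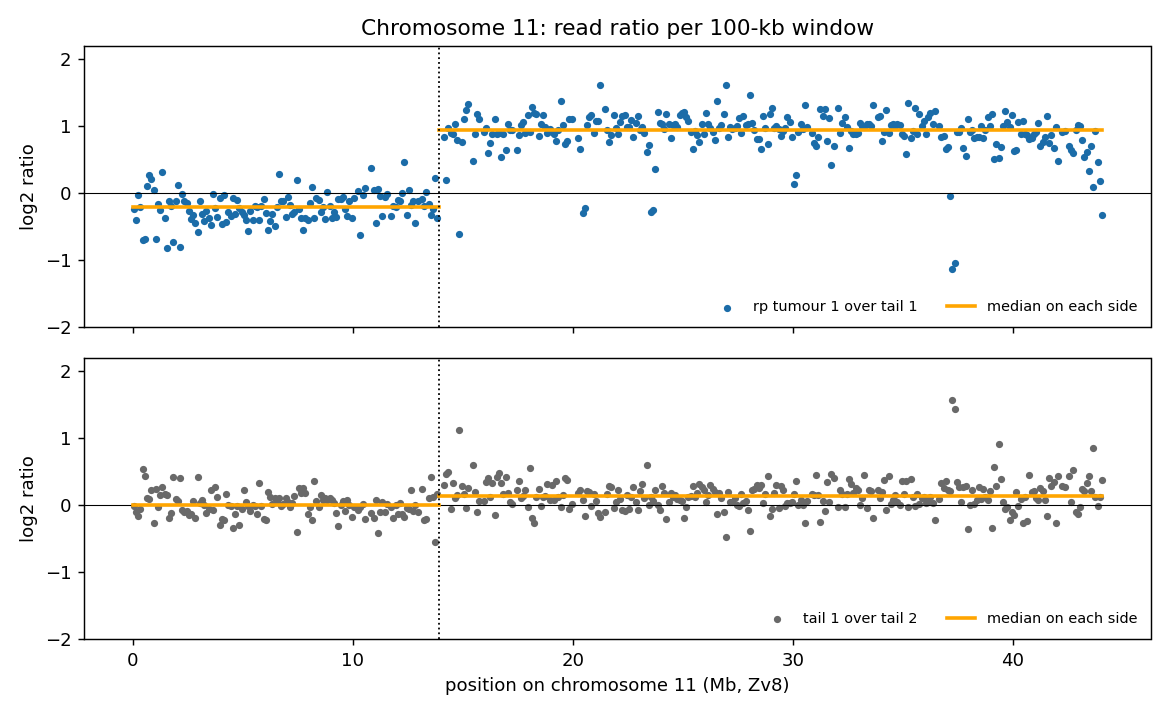
Log2 read ratio of each 100-kb window (y axis) along chromosome 11 in Mb (x axis) for rp tumour 1 over tail 1 (upper panel) and for tail 1 over tail 2 (lower panel), with orange lines for the median on each side of 13.9 Mb. The median moves from -0.21 to 0.95 in the tumour and from 0.00 to 0.14 in the ratio of the tails.

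In rp tumour 2, the longest partial changes were a 24.5-Mb segment of chromosome 9 (15700001 to 40200000) at -0.26 against a chromosome median of -0.04, and segments of chromosome 19 (3700001 to 18600000, 0.16 against 0.39) and chromosome 23 (29300001 to 44700000, 0.15 against 0.47). The segments on chromosomes 9 and 19 fell short of a distance of 0.2 against tail 1, at -0.13 and -0.18. A segment of chromosome 16 (41200001 to 51900000) stood higher than its chromosome, at 0.21 against -0.10. The end of chromosome 3 (51800001 to 60900000) was at -0.66 against 0.02. The single partial change of the p53 tumour was a segment of 21 windows on chromosome 21 (11000001 to 13300000) at 0.16 against -0.43. Tail 2 over tail 3 was also raised across this place (6700001 to 27400000, at 0.158 against -0.085), so low reads of tail 3 can enter this change.

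Rp tumour 2 carried high-level amplification on chromosome 25. Of its 16 amplified focal runs, 14 lay on this chromosome and together covered 99 windows between 4500001 and 24100000. The highest run, at 4500001 to 4900000, held 10111 reads in the tumour and 967 in tail 2, and stood at 11.8-fold the median window and 7.75-fold its own chromosome. It was followed by runs at 17400001 to 19400000 (8.08-fold), 6400001 to 6700000 (7.05-fold), 19500001 to 20000000 (5.37-fold) and 13800001 to 17200000 (5.12-fold). The highest single window reached a log2 ratio of 4.21. Over the 99 amplified windows the median ratio was 4.79-fold in rp tumour 2, against 1.49-fold in rp tumour 1 and 1.48-fold in the p53 tumour, where the whole chromosome was gained without an amplified run. The other 2 amplified runs of rp tumour 2 were on chromosome 20, at 22400001 to 22600000 and 23100001 to 23800000, with mean log2 ratios of 1.82 and 1.38.

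**Figure D3:**
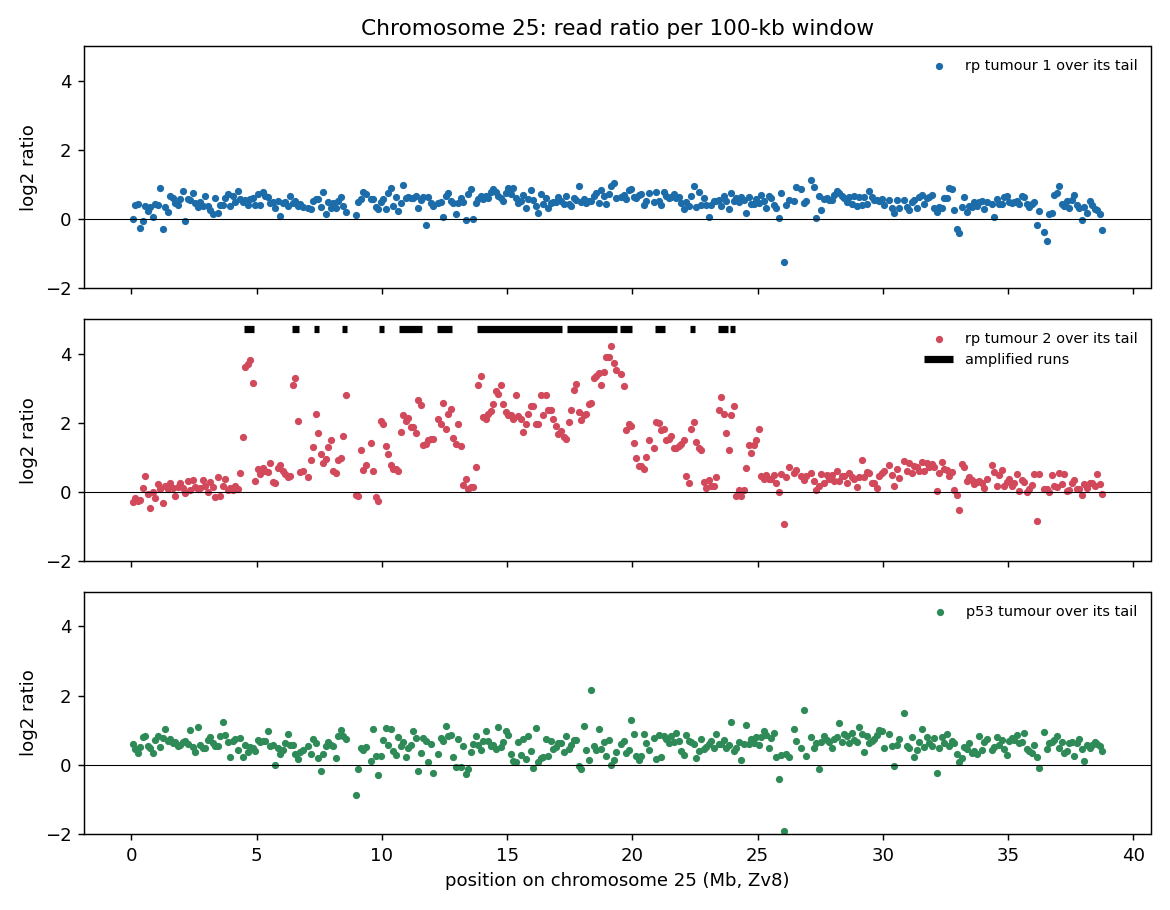
Log2 read ratio of each 100-kb window (y axis) along chromosome 25 in Mb (x axis) for the 3 tumours over their own tails, with black bars over the 14 amplified runs of rp tumour 2. Rp tumour 2 reaches 4.21 and alternates between amplified and low windows up to position 25100000, while rp tumour 1 and the p53 tumour keep 1 level, with chromosome medians of 0.51 and 0.60.

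Several of the other focal runs coincided with windows in which tails differed. Rp tumour 1 had 1 amplified run, at 600001 to 1500000 on chromosome 9, with a mean log2 ratio of 0.95. It also had 30 deleted runs, of which 17 fell within the first 13.9 Mb of chromosome 11 below the rest of that chromosome. Its lowest runs were on chromosomes 3 (900001 to 1100000, at -2.47, 27 reads against 114), 21 (28000001 to 28200000, -2.31), 14 (21200001 to 21400000, -2.11), 7 (57300001 to 57600000, -2.07) and 17 (37600001 to 37800000, -1.65). The last 4 of these runs were windows of high counts, where tail 1 held 20.7, 22.3, 9.52 and 3.61 times its median window. In them rp tumour 1 held 0.203, 0.205, 0.217 and 0.233 of the level in the other tails. The tails also differed from each other in these 4 runs. Tail 1 over tail 2 stood there at 1.93, 1.79, 1.64 and 1.39, and tail 2 over tail 3 at -2.72, -2.62, -2.48 and -2.53. Rp tumour 2 had 3 deleted runs, on chromosome 16 (20100001 to 20500000, -1.66) and chromosome 3 (7600001 to 7800000, -1.27, and 8300001 to 8500000, -1.05). The tails differed in the run on chromosome 16 too, where tails 1 and 2 over tail 3 had overlapping amplified runs, at 1.72 and 1.92. There tail 2 held 1.48 times the level of the other tails and the tumour 0.459 of it.

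The p53 tumour had 2 amplified runs, on chromosomes 21 (11100001 to 11300000, 0.81) and 2 (47700001 to 48000000, 0.73). Its 6 deleted runs included chromosome 16 at 20300001 to 20500000 (-2.01, 1 read against 11), chromosome 9 at 16600001 to 16800000 (-1.24), chromosome 7 at 61500001 to 61700000 (-1.04), chromosome 14 at 14800001 to 15000000 (-0.95) and chromosome 22 at 20100001 to 20400000 (-0.83). Tail 3 itself stood apart from the other tails in each of these runs, at 0.110 to 21.7 times their level, and at 1.27 times in the remaining deleted run, on chromosome 9 at 44700001 to 45000000 (-0.60), where the tumour held 0.845 of it. In the runs on chromosomes 16 and 22 tail 3 held 0.146 and 0.110 of that level and the tumour 0.0142 and 0.0507, so both were below the other tails. In the run on chromosome 21, tail 3 held 0.215 and the tumour 0.390 of the level in the other tails, so the tumour was not raised over those, and on chromosomes 2 and 14 the tumour held 1.11 and 0.970 of it. In the runs on chromosome 9 at 16600001 and on chromosome 7, tail 3 held 21.7-fold and 6.12-fold that level, and the tumour was above it too, at 7.05-fold and 2.80-fold. In the tails, focal runs by the same rule numbered 9 for tail 1 over tail 2, 38 for tail 1 over tail 3 and 94 for tail 2 over tail 3. None of the tail-over-tail ratios had more than 2 amplified windows on chromosome 25.

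The 2 rp tumours had similar chromosome profiles. Across 25 chromosomes their values correlated with Pearson's r = 0.79 (permutation p = 1e-05, the smallest the permutations can give, adjusted 3e-05) and Spearman's rho = 0.74 (permutation p = 5e-05, adjusted 0.00015). Both gained chromosomes 14, 18, 19 and 23, none of which was called gained in the p53 tumour. The p53 tumour correlated less with each of them. With rp tumour 1, r was 0.44 (permutation p = 0.029, adjusted 0.038) and rho was 0.40 (permutation p = 0.050, adjusted 0.075). With rp tumour 2, r was 0.42 (permutation p = 0.038, adjusted 0.038) and rho was 0.28 (permutation p = 0.18, adjusted 0.18). In an alternative, the 2 chromosomes farthest from the median of 1 tumour were left out. These were 10 and 11 of rp tumour 1 for its 2 correlations, and 25 and 15 of rp tumour 2 for its correlation with the p53 tumour. Then r stayed at 0.77 between the rp tumours (adjusted permutation p = 0.00018). It fell to 0.29 and 0.27 with the p53 tumour (adjusted permutation p = 0.21 for both). Leaving out extreme values can lower r by itself, and the fall was not tested. Chromosomes are not independent replicates, and the difference between the correlations was not tested.

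Chromosomes 18, 7, 9 and 2 differed between the p53 tumour and the rp tumours. Chromosome 18 was gained in both rp tumours, at 0.46 and 0.44, and lost in the p53 tumour, at -0.45, and the tumour effect of the p53 pair minus that of the rp pairs was -0.84 (SE 0.12, adjusted p = 0.0067, edgeR quasi-likelihood test). Chromosome 7 went the other way, with -0.20 and -0.42 in the rp tumours, 0.33 in the p53 tumour and a difference of 0.70 (SE 0.11, adjusted p = 0.0067). On chromosome 9 the difference was 0.60 (SE 0.14, adjusted p = 0.037), from -0.21 and -0.04 in the rp tumours to 0.50 in the p53 tumour. Chromosome 2 stood at 0.18 and 0.10 in the rp tumours and at -0.42 in the p53 tumour, a difference of -0.52 (SE 0.13, adjusted p = 0.039). With library totals, chromosomes 9 and 2 did not pass (adjusted p = 0.11 for both), and chromosome 2 did not without the pair block (0.057). The p53 group held 1 tumour, and its sequencing runs were separate from those of the rp pairs, so that run and genotype cannot be told apart by this test alone. When all windows with at least 1 read were used, no chromosome passed by edgeR (8 had an unadjusted p under 0.05). With an rp pair left out, the pair block was dropped as well, since no residual degree of freedom remained with it. In that fit no chromosome passed by edgeR without pair 1 (5 under 0.05), and chromosome 2 did not without pair 2 (adjusted p = 0.096).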

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

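Apart from the edgeR interaction test, the checks of the difference between the p53 tumour and the rp tumours described here were chosen after its values had been seen.

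The tumour effect on 4 chromosomes differed between the p53 pair and the rp pairs by the edgeR interaction test, at -0.5217 for chromosome 2, 0.6973 for chromosome 7, 0.6016 for chromosome 9 and -0.8435 for chromosome 18. Sequencing runs could give such a difference, since the p53 pair was sequenced in runs of its own. Tail 3 over tails 1 and 2 was shifted by at most 9.69% of the difference between the tumours on any of the 4 chromosomes. This cannot decide the matter, because each tumour was set against a tail of its own runs. A shift shared by tumour and tail cancels, and a shift of the tumour alone would not show in the tails. Tumour-to-tumour spread remains open as well. The 2 rp tumours differed from each other by up to 34.33% of the p53-to-rp difference (on chromosome 7). On chromosome 18 they differed by 2.77% of it, the least of the 4. Spread among p53 tumours cannot be had from 1 tumour, so genotype, run and the individual tumour cannot be told apart.

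Other splits of the 6 libraries into groups of 3 were set against the comparison of tumours with tails. The real split gave 8 chromosomes and the highest of the other splits gave 1. For windows the counts were 645 and 40. Of the 10 splits, 4 parted all 3 pairs, and the 3 of these that mixed tumours and tails called 0 chromosomes and 0 windows. In both cases only 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05.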

How the results depend on the processing

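No named chromosome changed direction under any alternative. For the chromosomes tested by edgeR, 8 of 25 passed in tumours against tails, and 6 did with DESeq2, without the pair block or without windows over 2 times the median tail window, 5 with library totals and 5 with all windows. Leaving out 1 pair at a time gave 0 to 9, in fits with 2.27 to 25 degrees of freedom whose counts are not like for like. For windows, the pair block decided the count of 645, since without it 0 passed by edgeR, while library totals gave 340 and leaving out 1 pair gave 7 to 1978. DESeq2 gave 504 windows (437 higher, 67 lower). In both, the highest count came without pair 3, the p53 pair, while no chromosome passed without pair 1 or pair 2. For the p53 tumour against the rp tumours, 4 chromosomes passed with or without the pair block, 2 with library totals and 0 with all windows, and leaving out an rp pair, in a fit without the block that takes the lone tumours to vary like the other groups, gave 0 to 5. The pairing changed no other call than those given here and in the comparisons, where the fit without the block ended the calls of 3 chromosomes (11 and 22 in tumours against tails, 2 between the p53 tumour and the rp tumours) and added 1 between the p53 tumour and the rp tumours. Causes were not tested, except where fewer pairs or libraries were fitted.

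Among the chromosomes called per tumour, a threshold of 0.3 left 10 in rp tumour 1, centring on library totals left 7 in rp tumour 2, and the ratio of summed counts left 1, 1 and 0 in rp tumour 1, rp tumour 2 and the p53 tumour. With summed counts the background limit rose to 0.79. Without the 1 window holding the most reads of tail 3 it was 0.33, with 9, 10 and 12 calls, and without windows over 2 times the median tail window it was 0.20, with 17, 14 and 15 calls, both chosen after the data had been seen. The other tail of the same runs as reference, also chosen after the data had been seen, gave 20 in rp tumour 1 and 13 in rp tumour 2. A threshold of 0.1 changed no call, because the tail limit of 0.20 then ruled. Partial changes depended on the settings. In rp tumour 1 they numbered 41 and 13 with penalties of 25 and 80, 40 with the sum of the tails as reference, 14 with windows of 500 kb and 9 when also required against the other tail. In rp tumour 2 they numbered 24 with a penalty of 80, 63 with the summed tails and 18 with 500-kb windows. In the p53 tumour the counts were 6 and 0 with penalties of 25 and 80, 48 with the summed tails, which brought in tails of other runs, and 0 with 500-kb windows. Focal runs, 31, 19 and 8 in the 3 tumours, became 39 in rp tumour 2 and 16 in the p53 tumour at a log2 distance of 0.8, 6 in rp tumour 1 and 1 in the p53 tumour at 1.5, 13, 11 and 3 with at least 3 windows, and 39 in rp tumour 2 with the summed tails. With the summed tails as reference of every tumour, which share controls, r with the p53 tumour was 0.3872 for rp tumour 1 and 0.3835 for rp tumour 2 (adjusted permutation p = 0.059 for both), while rho was 0.44 for rp tumour 1 (adjusted permutation p = 0.046, against 0.075 over its own tail) and 0.34 for rp tumour 2 (0.099), and without the 2 farthest chromosomes, over the own tails, r was 0.2866 and 0.2736. Corrections for GC content were not run, since no Zv8 sequence was used here. In the p53 pair, with 66 and 71 reads in the median window, counting error alone came to 12.3% and 11.9% of that window.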

Other observations

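Except for the slope within chromosomes and the first test on chromosome 25, the tests in this part were chosen after the results they bear on had been seen.

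A block of 9 windows on chromosome 9, at 600001 to 1500000, was raised in both rp tumours, with a median log2 ratio of 0.92 (interval 0.83 to 0.94) in rp tumour 1 and 0.83 (0.75 to 0.94) in rp tumour 2, while the rest of the chromosome was at -0.21 and -0.04. The p53 tumour stood at 0.75 (0.54 to 0.97) in the block and at 0.50 on the chromosome. Few reads in the tails cannot account for it, since the lowest tail level in the block was 0.972 of its median window. A candidate explanation is that this block belongs to another chromosome and was placed on chromosome 9 in the assembly. Of 1085 overlapping stretches of 40 windows on the other chromosomes, 1 lay inside the intervals of the block in all 3 tumours, so that 1 other chromosome matched, at 3000001 to 7500000 on chromosome 10, and the 10 nearest stretches were all on chromosome 10. A gain shared by both rp tumours would give similar values and was not tested, so this remains a hypothesis.

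Across 25 chromosomes, tail 1 over tail 2 correlated with rp tumour 1 over tail 3, ratios with no library in common, at r = 0.72 (permutation p = 0.0001, the smallest the permutations can give) with a slope of 0.12 (interval 0.08 to 0.16). It also followed rp tumour 2 over tail 3, at r = 0.62 (permutation p = 0.0009) with a slope of 0.14, and with both tumours in 1 regression the slopes were 0.11 (-0.0021 to 0.21) on rp tumour 1 and 0.02 (-0.12 to 0.17) on rp tumour 2, so chromosome values alone did not tell the rp tumours apart. Reads of rp tumour 1 in the library of tail 1 may explain this: the step of chromosome 11 in rp tumour 1 recurred at the same place in tail 1 over tail 2, at 0.1389 (0.10 to 0.18) against 0.14 from the slope, and was 0.01 (-0.09 to 0.14) in tail 2 over tail 3, and rp tumour 2 had no step there (0.00). A first test, the slope over segments within chromosomes, gave -0.18 or 0.37 depending on the tail used as reference, and decides nothing because tails of different runs differ within chromosomes. For reads of rp tumour 2, which shared the runs, a first test set its amplified windows of chromosome 25 against the rest of that chromosome. Tail 1 over tail 3 was higher there by 0.21 (0.16 to 0.31), but tail 2 over tail 3 was too, by 0.26 (0.17 to 0.38), so it decides nothing. Over these windows, tail 1 over tail 3 had a slope of -0.0097 (-0.03 to 0.02) on the ratio of rp tumour 2. This argues against such reads, since at least 0.06 was needed. Whether tumour cells in the tail or mixing of DNA or barcodes would have brought tumour reads into tail 1 stays open.

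In 20 kept windows with at least 200 reads in tail 3, that tail held more than 5 times the mean share of tails 1 and 2. These windows made up 4.16% of the reads of tail 3 in kept windows and 1.2% of those of the p53 tumour, and 1 window of chromosome 16 alone, at 21500001, held 19907 reads, 2.05% of tail 3. The p53 tumour held a larger share of its reads than the rp tumours in every such window. This ratio ran from 2.0 (chromosome 14 at 45100001) to 40.1 (chromosome 16 at 21500001). The excess was thus present in both libraries of the p53 pair, with the p53 tumour at 0.18 to 0.91 of the share in tail 3. The mitochondrial genome held 0.0327%, 0.0151% and 0.0419% of the reads in tails 1 to 3, and 0.0329%, 0.0284% and 0.0341% in rp tumour 1, rp tumour 2 and the p53 tumour. A segment of chromosome 14, at 14200001 to 15000000, stood at -0.36 in rp tumour 1 and at -0.27 in rp tumour 2, below chromosome medians of 0.48 and 0.38. Against the other tail of the same runs, their distances from the chromosome median were -0.74 and -0.68. Normal tails also differed within this segment. Its window at 14200001 held 83, 75 and 1020 reads in tails 1 to 3. The p53 tumour had a deleted run at 14800001 to 15000000 (-0.95), where tail 3 held 1.81 times the level of the other tails.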
